A study of Mus musculus with 2 samples.

How the data were processed

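Chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 trimethylated at lysine 36 (H3K36me3) was carried out on kidney from mouse embryos at 16.5 days of development, strain B6NCrl, with both sexes pooled, per the labels. The series holds a single group with n = 2 biological replicates. Replicate 1 came from an unstated number of embryos and 2 technical replicates. Replicate 2 came from 41 embryos and 1 technical replicate. The labels give a size range of 300 to 500 bp for both libraries. There was no second group, so no contrast between conditions was made.

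The deposited data were 4 peak lists on build mm10, per the file headers and the notes that accompany them: a list for each replicate, a list made from both replicates together (the pooled list) and a list named replicated peaks (the replicated list). Each replicate's peaks were called on that replicate alone. The aligner, the peak caller, its thresholds and the rule by which a pooled peak entered the replicated list are not given in the sources used here. The deposited enrichment of each peak is the authors' own value. It was taken as a ratio because all values lie above 1, since neither its unit nor the reference it is relative to is given in the sources used here, and it was used only to describe or rank peaks within a list. The deposited peak significance was given as −log10 p and −log10 q. No deposited value held read counts, so the depth of each library is unknown and no interval based on counting reads is given. A base outside a peak is a base that did not pass the authors' threshold, which is not a measurement of 0.

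Peaks were intersected with the GENCODE M21 annotation, which is on GRCm38, the assembly also called mm10. Chromosome lengths and assembly gaps came from the RefSeq sequence of that build. Coordinates are counted from 1. For each of 21221 protein-coding genes of at least 1 kb on chromosomes 1 to 19, X and Y, the share of the span from gene start to gene end that lay in peaks was computed per replicate. A gene was called marked where that share was at least 10% in each replicate's own list. The span takes in every annotated transcript, so rare long transcripts lower the share. Neighbours that overlap a gene, or whose peaks run past their own end into it, can raise it. Of the genes measured, 4641 overlapped another protein-coding gene.

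Position along genes was measured in marked genes of at least 5 kb as the peak coverage of 3 equal parts, and in 20 equal bins. Exon coverage used internal exons and introns of the same marked genes, with bases summed over all of these genes before the ratio was taken. Flanks of 5 kb were used only where they held no other annotated gene. Peak overlap between replicates required at least 50% of a peak's length to lie in the other list, and was set against 20 seeded shuffles of the peaks within their chromosomes outside assembly gaps.

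Before the data were examined, 26 gene lists were fixed for cell types of the developing kidney, other tissues and broadly used functions. Each was compared with all other measured genes by a two-sided Fisher's exact test of marked against unmarked, with Benjamini-Hochberg adjustment over the 26 lists, and odds ratios had 0.5 added to each cell. Beside the test stands the percentile of the list's median coverage among 10000 random lists of the same size drawn from the same gene length deciles. X was compared with the autosomes, and long non-coding RNA genes with protein-coding genes, by the same exact test. Genes are not replicates, so these p-values describe the 2 libraries. Of the listed symbols, 9 had no measured gene and 2 were matched through an older symbol. The pattern first written for ribosomal proteins also took in 10 genes of S6 kinases, whose symbols begin alike. These were removed after the values had been seen. With them the list held 70 marked of 93 genes in place of 66 of 83, and both versions were called.

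Genes are named by a rule fixed before the data were examined. It takes 20 sentinel genes, the 10 marked genes of at least 10 kb with the highest coverage in their less covered replicate, the 2 most and the least covered members of each list, the 5 genes of at least 10 kb that differ most between replicates, and the 5 longest runs of replicated peaks with gaps of at most 3 kb. Where the least covered members of a list tied at 0, their number is given with 1 or more of them. Named outside this rule, after the values were seen, were the marked Pdgfrb, Cx3cr1, Hoxa4 and Hoxb3 and the X and long non-coding genes that the text says were so chosen.

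The alternatives were a −log10 q of at least 2, the replicated or the pooled list in place of the replicates' lists, each replicate left out, equal numbers of top peaks, coverage of at least 5% or 20%, overlapping genes left out, no minimum length, only the 3-prime part of the gene past its midpoint, logistic regression with gene length, genes of at least 20 kb and flanks of 2 kb. Added after the data were seen were exon coverage in the last 2 of the 3 parts of the gene, the strongest peaks of each list, and the ribosomal list with the S6 kinases.

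The procedures were tested on simulated data. With 200 of 7918 genes planted at 30% coverage in both replicates and 200 planted in a single replicate, 100% of the former and 0 of the latter were called, which checks the code and not the limit, since the rule itself fixes that outcome. With 6 lists raised to 80% marked against 30% elsewhere, 95.7% were found over 50 runs on 21221 genes, with 0.08 false calls per run. Marks were drawn for each gene alone, without regard to its length or neighbours, and no list was lowered. The simulation therefore says nothing of how well lists marked less often are found. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, bedtools 2.31.1 and matplotlib 3.10.9.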

Results

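H3K36me3, a histone modification laid down over transcribed genes by SETD2, was mapped in embryonic mouse kidney at 16.5 days in 2 biological replicates of a single group. Replicate 1 had 163866 peaks with a median width of 270 bp, which together covered 2.24% of the genome outside assembly gaps. Replicate 2 had 197576 peaks with a median width of 324 bp and covered 3.56%. Read depth is unknown, so the firmness of each value rests on the spread between the replicates. For single genes that spread holds an offset between the libraries: 97.3% of marked genes were more covered in replicate 2, at a median ratio of 1.47.

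The modification lay almost wholly inside genes. Protein-coding gene spans held 94.4% ± 0.10 of peak bases (mean ± SD, n = 2), although they made up 39.3% of the genome, a 2.402-fold excess. Exons of these genes held 19.7% ± 1.3 of peak bases, 6.91-fold their share of the genome. Introns held 74.7% ± 1.2, a 2.05-fold excess. Genes for long non-coding RNA that lie outside protein-coding genes held 0.832% ± 0.031 and intergenic sequence 4.70% ± 0.062, against 5.87% and 53.9% of the genome.

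Along genes, coverage rose from the start towards the 3-prime end. In 5822 marked genes of at least 5 kb, the final part of 3 was covered 2.97 ± 0.21 times as much as the first (n = 2), and 86.8% of these genes had the higher coverage in the final part in both replicates. The first 5% of the gene was 1.38% covered in replicate 1 and 1.99% in replicate 2. The bin that ends at 90% of the gene was the most covered, at 42.0% and 58.4%. Internal exons were covered 2.08 ± 0.21 times as much as introns, over the summed bases of the same 6138 genes. The ratio was not taken gene by gene, so differences in coverage between short and long genes enter it. Peaks ran past the annotated gene end and not before the start: at 1235 genes with empty flanks, the 5 kb downstream was 10.8% covered in replicate 1 and 17.2% in replicate 2, and the 5 kb upstream 0.260% and 0.380%. The ratio of downstream to upstream coverage was 43.4 ± 2.5, and it was 76.4 with flanks of 2 kb.

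**Figure D1:**
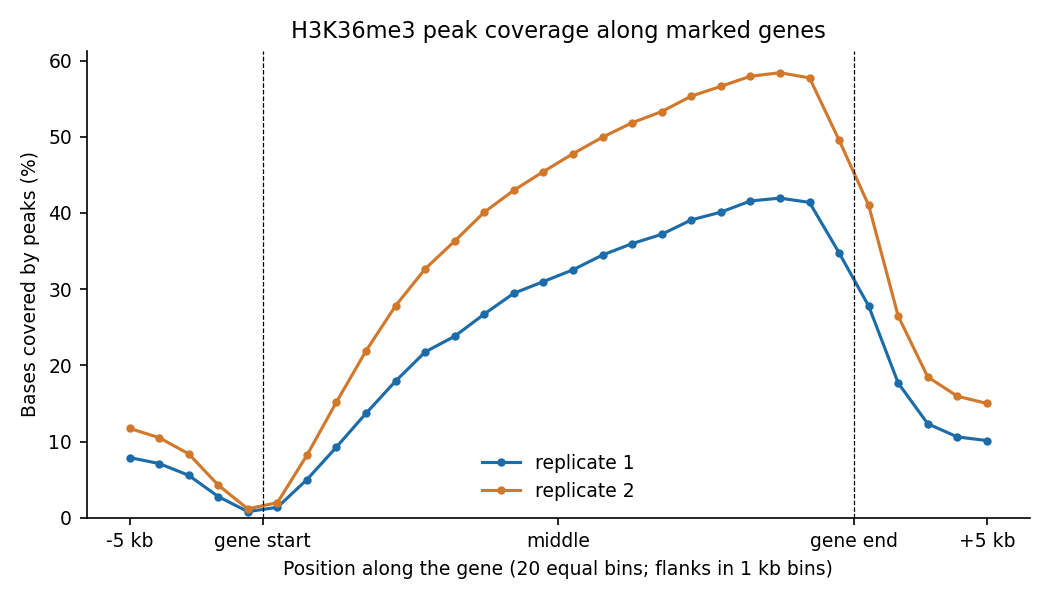
Share of bases covered by peaks (%, vertical axis) along marked genes, in 20 equal bins from gene start to gene end and in 1 kb bins over 5 kb on either side, 1 line per replicate. Flanks here are not restricted to those without other genes. Coverage is lowest in the 1 kb before the gene start (0.817% and 1.18%) and highest in the bin ending at 90% of the gene (42.0% and 58.4%).

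Of 21221 protein-coding genes, 6390 (30.1%) were marked in both replicates, and 9101 (42.9%) held no peak base in either. Regulators of kidney development fell on both sides of the call. Pax2, a transcription factor of the nephric lineage (chromosome 19, 44756045 to 44837871), was covered over 25.7% ± 9.5 of its span (n = 2). Pax8, its paralog (chromosome 2, 24420560 to 24475599), was at 19.1% ± 6.3, and Wt1, needed for nephron progenitors and podocytes (chromosome 2, 105126529 to 105173616), at 14.9% ± 6.5. Actb, which encodes beta-actin (chromosome 5, 142903115 to 142906754), was at 43.8% ± 10.1, and Setd2, the gene of the methyltransferase itself (chromosome 9, 110532597 to 110618633), at 32.8% ± 10.3. Those 5 were the marked sentinels among 20. Wt1 was at 10.2% in replicate 1, next to the 10% limit.

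The other 15 sentinels were not marked. No peak lay in either replicate over Six2, a nephron progenitor factor, Foxd1 of the stromal progenitors, the podocyte slit diaphragm genes Nphs1 and Nphs2, Umod of the thick ascending limb, the beta-globin gene Hbb-bs, the liver gene Alb or the muscle regulator Myod1. Low mean values were found at Csf1r, the macrophage growth factor receptor gene (7.13% ± 2.3), Lhx1 (2.80% ± 4.0), Lrp2, which encodes megalin (2.44% ± 1.1), Gata3 (2.35% ± 3.3), the endothelial receptor gene Kdr (1.86% ± 1.5), Ret (0.235% ± 0.33) and Hnf4a (0.167% ± 0.24). Several of these genes are short or active in few of the cells of a whole kidney, and the tissue was not sorted.

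**Figure D2:**
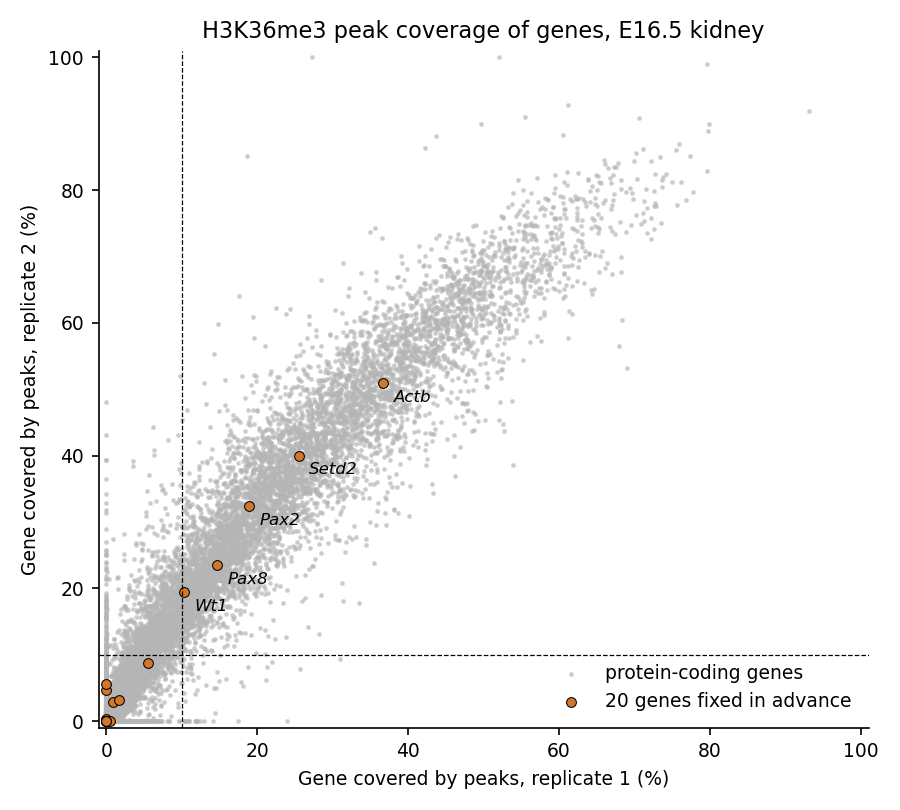
Share of each protein-coding gene covered by peaks in replicate 1 (%, horizontal axis) and replicate 2 (%, vertical axis). Grey points are genes, orange points the 20 sentinels, and dashed lines the 10% limit. Pax2, Pax8, Wt1, Actb and Setd2 lie above the limit in both replicates, and most marked genes lie above the diagonal (97.3% were more covered in replicate 2).

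**Figure D3:**
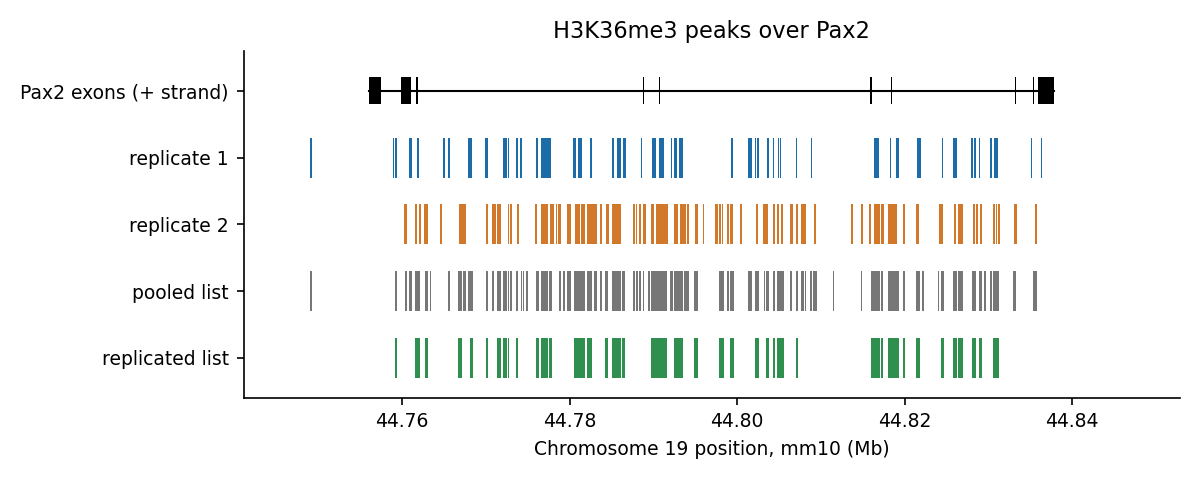
Peaks of each of the 4 lists (coloured blocks, to scale) over Pax2 and 15 kb either side on chromosome 19 of mm10 (Mb, horizontal axis), with merged exons in black and the gene reading left to right. Replicate 1 has 53 peaks over the gene, replicate 2 has 72, the pooled list 81 and the replicated list 41.

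The most covered genes of at least 10 kb included zinc finger genes and genes of basic cell functions. Zfp110 was at 84.3% ± 6.4, Zfp606 at 81.3% ± 2.4 and Zfp68 at 78.1% ± 4.4 (n = 2 each). Fasn, the fatty acid synthase gene, was at 81.2% ± 5.6, Mybbp1a at 80.8% ± 7.5, Hjurp, which encodes a centromere chaperone, at 78.8% ± 1.4, the RNA helicase gene Ddx39b at 78.7% ± 3.6, the core splicing factor gene Prpf8 at 78.3% ± 5.9, the arginine methyltransferase gene Prmt5 at 77.6% ± 1.1 and the mitochondrial RNA polymerase gene Polrmt at 76.7% ± 1.5. Mybbp1a overlaps another protein-coding gene. The longest runs of replicated peaks lay over Vps13d (138.5 kb, chromosome 4, 145052003 to 145190521), Wdfy3 (132.0 kb, chromosome 5), Mtor with Angptl7 and Exosc10 (131.4 kb, chromosome 4), Mdn1 (113.5 kb, chromosome 4) and Cep350 (105.6 kb, chromosome 1). The share of marked genes depended on length: it was 12.1% in the shortest decile of genes, 42.2% in decile 5 and 9.28% in the longest decile. The low share in the longest decile is not a lack of peaks, since the limit is a share of the whole span. Genes with no peak base in either replicate made up 76.9% of the shortest decile and 25.6% of the longest. That share depends on length too, as a longer span has more room for a peak. In replicate 2 alone 17.9% of the longest decile were above the limit.

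Of the 26 lists, 6 were marked more often than other genes, 11 less often and 9 neither. Cell cycle genes led, with 19 of 20 marked (adjusted p = 9.10e-09, Fisher's exact test with Benjamini-Hochberg adjustment), Mcm3 and Mcm2 of the replicative helicase being at 71.6% ± 5.1 and 68.0% ± 16.5 and Pcna lowest at 13.6% ± 9.0. Housekeeping genes had 20 of 24 marked (exact test, adjusted p = 4.41e-07), from Gpi1 at 75.9% ± 11 and Eef2 at 72.0% ± 11 to the X-linked Hprt at 5.89% ± 1.9. Genes of writers, erasers and readers of H3K36 methylation had 15 of 18 marked (exact test, adjusted p = 1.69e-05), with the demethylase gene Kdm4a at 76.0% ± 8.0, the elongation factor gene Supt6 at 60.1% ± 6.4 and Kdm4c lowest at 8.82% ± 4.0, and in replicate 2 alone all 18 were above the limit. Complex I subunits of the respiratory chain had 30 of 36 marked (exact test, adjusted p = 3.55e-10), from Ndufv1 at 56.0% ± 8.8 and Ndufs8 at 55.3% ± 9.7 to Ndufb11 with no peak. The log2 odds ratio of that list fell from 3.45 to 2.07 at a coverage of at least 20%, with the call kept. Ribosomal protein genes had 66 of 83 marked (exact test, adjusted p = 1.47e-19), Rps5 and Rps3 being at 74.5% ± 4.0 and 74.0% ± 2.6, and 5 members, among them Rpl3l, having no peak. Zfp zinc finger genes had 234 of 391 marked (exact test, adjusted p = 2.03e-33), with Zfp869 at 89.3% ± 14 and Zfp110 next, and 57 members, among them Zfp993, had no peak. The median coverage of each of these lists was at or above percentile 99.97 of length-matched random lists.

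**Figure D4:**
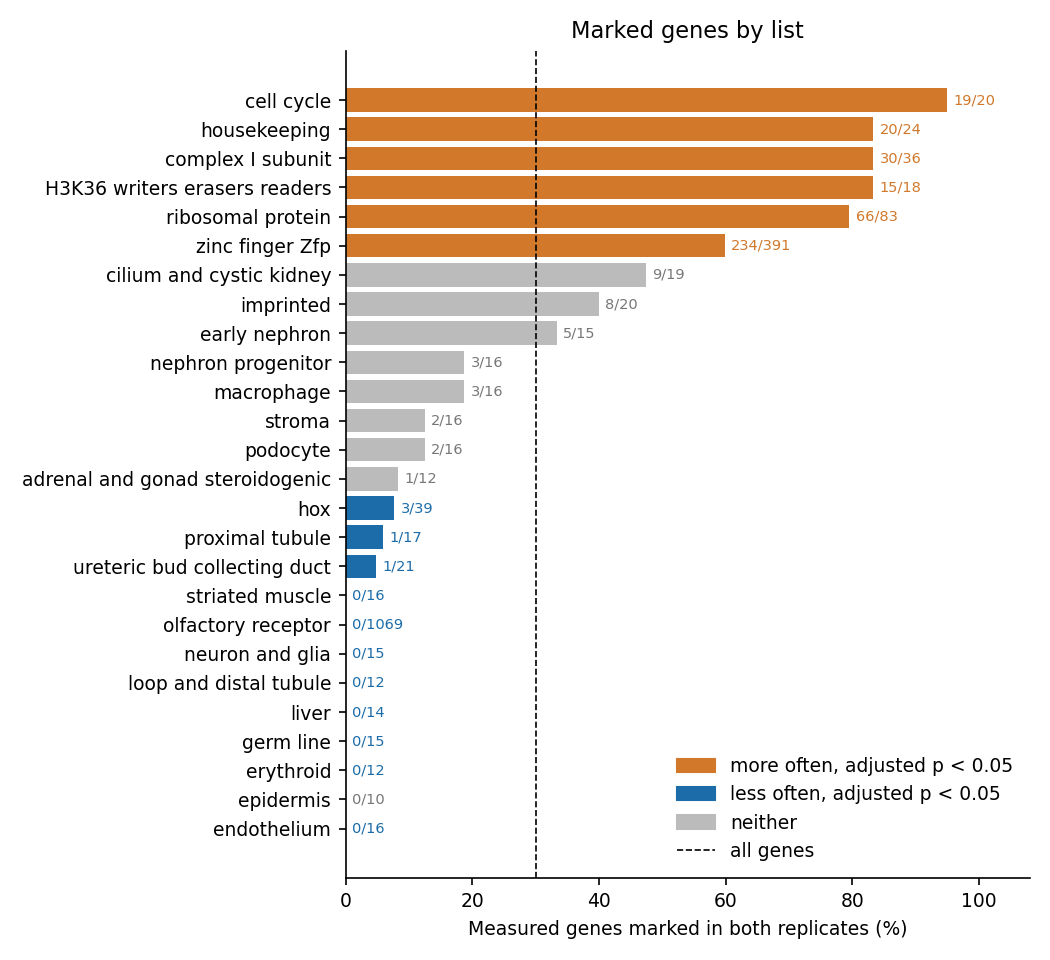
Share of measured genes marked in both replicates (%, horizontal axis) for each of the 26 lists, with marked over measured genes beside each bar. Orange lists were marked more often and blue lists less often than other genes at an adjusted p under 0.05, grey lists neither, and the dashed line is the 30.1% of all genes. Cell cycle genes are highest with 19 of 20, and 9 lists have no marked member.

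Lists of kidney cell types were marked no more often than other genes. Early nephron genes had 5 of 15 marked (exact test, adjusted p = 0.782), led by Ccnd1, which overlaps another gene, at 51.3% ± 9.4 and the Notch ligand gene Jag1 at 41.9% ± 11, with 5 members, among them Pou3f3, at 0. Their log2 odds ratio of 0.28 turned to -0.42 at a −log10 q of at least 2, with no call in either case. Nephron progenitor genes had 3 of 16 (exact test, adjusted p = 0.437), Pax2 and Sall1 (21.7% ± 6.6) leading and 4 members, Six2 among them, at 0. Podocyte genes had 2 of 16 (exact test, adjusted p = 0.205), Vegfa at 45.7% ± 8.2 and Actn4 at 35.3% ± 5.7, with 6, Nphs2 among them, at 0, and Actn4 is widely expressed and overlaps another gene. Stromal genes had 2 of 16 (exact test, adjusted p = 0.205), Col1a1 at 21.1% ± 15 and Pdgfrb at 16.2% ± 8.7 being marked, Col1a2 at 17.1% ± 10 being marked in replicate 2 alone, and 5 members, among them Tbx18, being at 0. Their median coverage was at percentile 80.9 of matched lists, and their log2 odds ratio of -1.32 turned to 0.98 with the pooled list, without a call, and to -3.63 at a −log10 q of at least 2, with a call (exact test, adjusted p = 0.0224). Ureteric bud and collecting duct genes were marked less often, with 1 of 21 (exact test, adjusted p = 0.0156). The marked gene was Krt18 at 18.3% ± 3.5, Etv5 followed at 15.2% ± 8.9 and 9 members, among them Wnt9b, were at 0. Their call was lost at a coverage of at least 5% (exact test, adjusted p = 0.154), and their log2 odds ratio of -2.56 was -1.68 without replicate 1, with the call kept. In replicate 2 alone, 5 of the nephron progenitor genes, 4 of the podocyte genes, 8 of the stromal genes and 3 of the ureteric bud and collecting duct genes were above the limit. Proximal tubule genes were marked less often too, with 1 of 17 (exact test, adjusted p = 0.0487), Slc5a2, which overlaps another gene, at 14.7% ± 0.11, Dab2 at 5.77% ± 3.2 and 8, Slc5a12 among them, at 0. Their call was lost at a −log10 q of at least 2 (exact test, adjusted p = 0.0792) and with no minimum gene length (adjusted p = 0.0504). None of 12 genes of the loop of Henle and distal tubule was marked (exact test, adjusted p = 0.0378), Clcnkb at 0.750% ± 1.1 and Tfap2b at 0.319% ± 0.45 being highest and 9, Umod among them, being at 0. That call was lost at a −log10 q of at least 2 (exact test, adjusted p = 0.0687). Genes of cilia and cystic kidney disease had 9 of 19 marked (exact test, adjusted p = 0.170), with Pkd2 at 49.9% ± 12, Dzip1l at 49.6% ± 13 and Pkhd1 lowest at 0.824% ± 0.55. That list was called as marked more often with the pooled list (exact test, adjusted p = 0.00748) or the replicated list (adjusted p = 0.00696), without replicate 1 (adjusted p = 0.0139) and at a coverage of at least 5% (adjusted p = 0.0129).

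Genes of other cell types and tissues were seldom marked. None of 16 endothelial genes was (exact test, adjusted p = 0.0126), Eng at 12.1% ± 5.4 and Ets1 at 8.83% ± 3.5 being highest and 4, Tie1 among them, at 0. That call was lost without replicate 1 (exact test, adjusted p = 0.0544), with the pooled list (adjusted p = 0.154), at a coverage of at least 5% (adjusted p = 0.253) and in the 3-prime part of the gene (adjusted p = 0.361). No member was marked among 12 erythroid genes (exact test, adjusted p = 0.0378), with Alas2 at 3.69% ± 2.8, Epb42 at 1.77% ± 0.081 and 10, Tal1 among them, at 0, a call lost at a −log10 q of at least 2 (adjusted p = 0.0687). The same held for 15 neuronal and glial genes (exact test, adjusted p = 0.0156), with Plp1 at 0.542% ± 0.77, Elavl4 at 0.129% ± 0.0062 and 12, Tubb3 among them, at 0. It held for 16 genes of striated muscle (exact test, adjusted p = 0.0126), with Ttn at 2.09% ± 1.3, Actn2 at 0.274% ± 0.39 and 12, Tnnt3 among them, at 0, and for 15 germ line genes (adjusted p = 0.0156), with Sycp3 at 1.38% ± 1.9, Dazl at 1.28% ± 1.8 and 11, Zp3 among them, at 0. All 14 liver genes were at 0 in both replicates (exact test, adjusted p = 0.0156), as were all 10 epidermal genes (adjusted p = 0.0557), a list that 6 of the alternatives called as marked less often, the pooled list among them (adjusted p = 0.0145). Among 1069 olfactory receptor genes none was marked (exact test, adjusted p = 1.15e-170), and Olfr1388 at 1.22% ± 1.7 was the only member with a peak base. Macrophage genes had 3 of 16 marked (exact test, adjusted p = 0.437), Cd68 at 69.8% ± 28, Fcer1g at 15.8% ± 4.8 and Cx3cr1, which overlaps another gene, with 12, Tyrobp among them, at 0. Cd68 is only 1.94 kb long, and peaks that run past the end of a neighbour were not told apart from its own. Steroidogenic genes of adrenal and gonad had 1 of 12 (exact test, adjusted p = 0.168), Star at 24.5% ± 11, with Amh at 4.97% ± 0.15 and 9, Nr5a1 among them, at 0, and was called lower with the pooled list (adjusted p = 0.0485). With coverage of at least 20%, 2 lists were called lower in place of 11, Hox genes and olfactory receptors. The log2 odds ratios of the 9 others were -3.83 to -2.25 before and -3.37 to -2.58 then. With overlapping genes left out 1 list was called lower, olfactory receptors, and the log2 odds ratios of the 10 others were -3.42 to -1.91. The median coverage of the 11 lists called lower lay between percentiles 3.2 and 50 of length-matched lists, with 1 list under percentile 5. Most of these lists had a median of 0, the lowest value possible, which ties with random lists at 0. For Hox genes and olfactory receptors the median of the matched lists was itself 0, so the percentile could not place them low. A percentile within the range of random lists therefore decides little for the lists with a median of 0. The median was above 0 for ureteric bud and collecting duct genes (0.235%, percentile 36.5), endothelial genes (0.686%, percentile 27.9) and proximal tubule genes (0.167%, percentile 12.5). For these the comparison at matched length did not place the median coverage outside the range of random lists.

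Hox genes, which encode position along the body axis, were marked less often, with 3 of 39 (exact test, adjusted p = 0.00426), Hoxb5 at 20.0% ± 11, Hoxa4, which overlaps another gene and holds no peak of the replicated list, at 15.5% ± 3.6 and Hoxb3 at 14.8% ± 4.6. Hoxa5 ranked next to Hoxb5 at 16.4% ± 23 but was covered in replicate 2 alone, and 20 members, among them Hoxd8, were at 0. Their call was lost without replicate 1 (exact test, adjusted p = 0.0891). The marked genes belonged to paralog groups 1 to 4 (2 of 12) and 5 to 9 (1 of 15), with 0 of 6 in groups 10 to 11 and 0 of 6 in groups 12 to 13, which was not tested. In replicate 2 alone 9 Hox genes were above the limit, 5 in groups 1 to 4, 3 in groups 5 to 9 and 1 in groups 10 to 11. Cluster A was 2.46% covered in replicate 1 and 6.76% in replicate 2, cluster B 2.83% and 5.76%, cluster C 0.172% and 0.515%, and cluster D 1.05% and 3.66%. Imprinted genes had 8 of 20 marked (exact test, adjusted p = 0.380), Nnat, which overlaps another gene, at 69.9% ± 15, Igf2r at 39.5% ± 7.9 and 5 members, among them Phlda2, at 0.

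The X chromosome stood apart from the autosomes. It was covered over 0.258% of its length in replicate 1 and 0.594% in replicate 2, against 1.56% to 3.91% and 2.56% to 6.13% across the autosomes. Of 877 protein-coding genes on X, 50 (5.70%) were marked, against 6340 of 20181 (31.4%) on the autosomes, a log2 odds ratio of -2.91 (adjusted p = 1.84e-76, Fisher's exact test). It was -1.93 with the pooled list, -2.28 with the replicated list, -2.22 without replicate 1 and -3.64 at a coverage of at least 20%, each with the call kept. The marked X genes were also less covered, at medians of 16.7% and 30.2% against 25.1% and 38.7%. The most covered was Asmt, close to the distal end of the chromosome (170672644 to 170678054, 51.4% ± 11), followed by Hcfc1 (48.0% ± 17), Flna, which encodes filamin A (47.1% ± 15), and the demethylase gene Kdm5c (44.5% ± 17), chosen for mention after their values were seen. None of 163 Y genes was marked, and 1.23% of them held a peak base in replicate 1 and 0% in replicate 2. Whether reads could be placed on Y genes was not measured, and both sexes were pooled. These values therefore do not show that Y genes lack the modification.

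**Figure D5:**
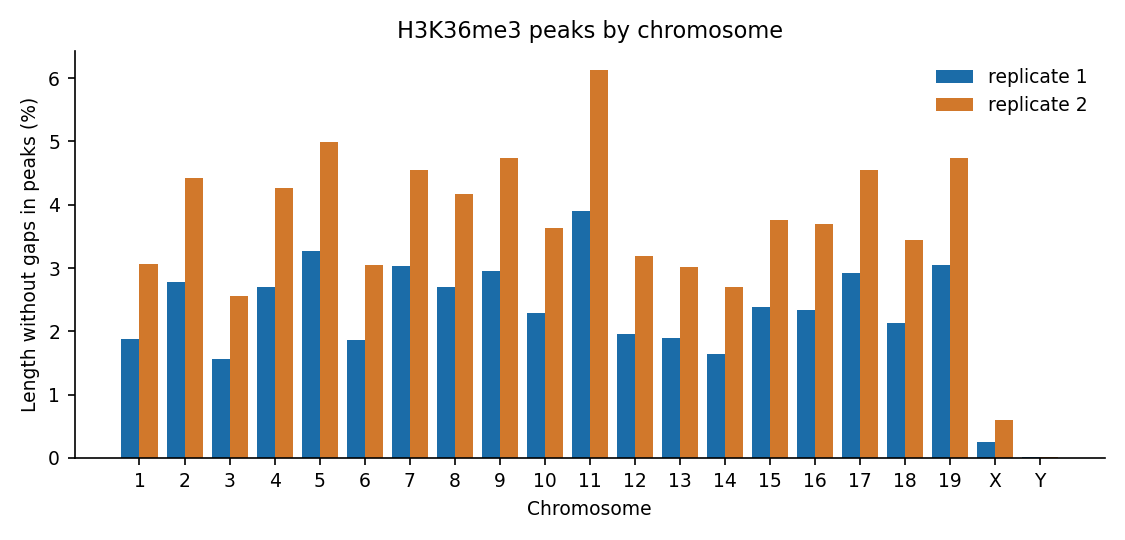
Share of each chromosome's length without assembly gaps that lies in peaks (%, vertical axis), 1 bar per replicate. Chromosome 11 is highest at 3.91% and 6.13%, and X is at 0.258% and 0.594%.

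Long non-coding RNA genes were seldom marked. Of 6447 that overlap no protein-coding gene, 77 (1.19%) were, against 30.1% of protein-coding genes, a log2 odds ratio of -5.15 with an exact p too small to be represented. With overlapping genes left out of the protein-coding side too, the log2 odds ratio was -4.92. Gene length was not matched. The nuclear RNA gene Malat1 (chromosome 19, 5795690 to 5802672) was covered over 43.5% ± 13 and the small nucleolar RNA host gene Snhg17 (chromosome 2, 158353700 to 158361580) over 64.1% ± 14, both chosen for mention after their values were seen.

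The replicates shared far more of their peaks than peaks shuffled over whole chromosomes would, but less than all. Of replicate 1 peaks, 72.6% had at least 50% of their length in replicate 2 peaks, and of replicate 2 peaks 39.8% in those of replicate 1, against 4.11% ± 0.053 and 2.43% ± 0.042 for shuffled peaks (SD over 20 shuffles). Shuffled peaks could fall outside genes, whereas protein-coding gene spans held 94.4% of peak bases. The excess therefore cannot tell agreement of single peaks from 2 lists that lie over the same genes. No shuffle within genes was made. Coverage correlated across genes at Spearman's rho = 0.956 and Pearson's r = 0.967, genes not being independent replicates. Replicate 1 had 6447 genes above the limit and replicate 2 had 8001, with 57 in replicate 1 alone and 1611 in replicate 2 alone. The genes of at least 10 kb that differed most were Sf3b6 (13.3% and 47.8%), Trmo (19.9% and 51.3%), Mbd4 (5.72% and 37.1%), Snrpc (25.7% and 56.8%) and Spryd3 (21.8% and 52.8%), each less covered in replicate 1. The replicated list kept 121389 of 202341 pooled peaks (59.99%), with a median width of 498 bp against 221 bp for the peaks left out and a median deposited enrichment of 3.91 against 2.83. A peak of each replicate touched 80.8% of the kept peaks.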

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

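Peaks on unplaced or unlocalised scaffolds lay outside the gene measurement and were counted because data that no comparison used held a signal above the 3 counts that a count of 0 allows. Replicate 1 had 32 such peaks, replicate 2 had 27 and the replicated list 10. The strongest peak of the replicated list by the authors' enrichment was among them, at 23.7 on scaffold GL456216 of chromosome 4 (30501 to 36190), over an annotated protein-coding gene that has only a clone-based name. No explanation was tested for these peaks.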

How the results depend on the processing

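Among the main results, 64 of 87 recomputed values kept the direction and side of a test, or, where there was no test, stayed within the SD between replicates or within 1.5 times a count. The other 23 moved, and none changed direction or side of a test. The size of X against autosomes was not judged by that count: its log2 odds ratio lay between -3.64 and -1.93. Of the recomputed list results, 287 were the same, 29 lost a call, 12 gained a call and 10 changed sign. Of 17 called lists, 7 kept their call under every alternative. Marked genes numbered 4097 at a coverage of at least 20%, where 2 lists were lower, and 1 list was lower with overlapping genes left out; fewer marked or measured genes follow from how both are made. The final-to-first ratio was 2.41 in genes of at least 20 kb. The flank ratio was 54.7 at a −log10 q of at least 2, 48.4 with the replicated list, 35.4 with the pooled list, 76.4 with 2 kb flanks, and 40.9 to 41.7 with a replicate left out. Exon to intron coverage was 1.86 in the last 2 of 3 parts of the gene, an alternative added after the data were seen. Peak bases in genes were 94.6% at the stricter q and 94.7% with the replicated list. Overlap of replicate 1 and replicate 2 peaks was 80.5% and 56.0% by 1 base, 34.6% and 28.7% when reciprocal, 74.0% and 37.5% at the stricter q, 68.2% and 43.9% with equal numbers of top peaks, and 92.0% and 68.4% for the strongest 25% (added after). The replicated list kept 65.9% of pooled peaks at the stricter q. Early nephron genes, not called in any, had log2 odds ratios of -0.42 at the stricter q, -0.046 with the replicated list, -0.30 with the pooled list, -0.21 and 0.26 without replicate 1 and without replicate 2, -0.20 at 5% and -0.37 at 20%. Stromal genes turned to 0.55 with the replicated list, 0.98 with the pooled list, 0.73 without replicate 1 (-1.34 without replicate 2) and 0.73 at 5%, none called, and were called lower at the stricter q (-3.63). The S6 kinases kept in the ribosomal list, also added after, changed no call (log2 odds ratio 2.81). The cause was not tested for the other moves. Unknown depth limits every statement on unmarked genes. No paired analysis was possible because the series has a single group.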

Other observations

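Genes were grouped by the letters of their symbol, a grouping chosen after the data were seen and not a test of function. Of 149 such families with at least 15 measured members, 34 were marked more often and 50 less often than other genes (Fisher's exact test, Benjamini-Hochberg adjustment over the families). Among the former, 14 of 16 Dhx helicase genes were marked (exact test, adjusted p = 2.23e-05), 45 of 55 Eif translation initiation genes (adjusted p = 1.07e-13), 37 of 46 Mrpl genes of the mitochondrial ribosome (adjusted p = 7.07e-11), 17 of 21 Nup nucleoporin genes (adjusted p = 1.77e-05) and 22 of 28 Polr RNA polymerase genes (adjusted p = 1.89e-06). Among the latter, none of 276 Vmn vomeronasal receptor genes (exact test, adjusted p = 6.18e-42), 29 Cldn claudin genes (adjusted p = 2.49e-04) or 39 Defb defensin genes (adjusted p = 1.20e-05) was marked, and 3 of 100 Cyp cytochrome P450 genes were (adjusted p = 1.28e-10).

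Among the tests that follow, those of the peak threshold on X, of the strongest peaks over Zfp genes, of another tissue in replicate 1 and of kidney against other tissues were chosen only after the result was seen. The X test on broadly used genes was rerun after the S6 kinases had been removed from the ribosomal list, and its versions for replicate 2 alone and without the cilium list were also added after the result was seen.

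Genes on X were marked less often than autosomal genes, and X-linked gene content was argued against as the whole cause: over the housekeeping, ribosomal, complex I, cell cycle, H3K36 and cilium lists, 1 of 9 members on X was marked against 158 of 191 on autosomes (p = 1.32e-05, Fisher's exact test). In replicate 2 alone it was 4 of 9 against 175 of 191 (exact p = 7.61e-04), without the cilium list 1 of 8 against 149 of 173 (p = 1.65e-05), and with the S6 kinases 1 of 11 against 162 of 199 (p = 1.28e-06). Repeat content, GC content and length as covariates left a log2 odds ratio of -2.65 (95% interval -3.06 to -2.23). A lower signal on X that falls below the peak threshold stays open. Replicate 2 had 2.08 times as many marked X genes as replicate 1, against 1.23 times on autosomes. This cannot decide it, since any set of less covered genes can gain more from a longer peak list, whatever lowers its coverage. The use of a single X per cell in both sexes and of pooled sexes stays open, as no biological explanation was tested.

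Zfp genes were marked more often than other genes and held 51 of the 100 strongest replicated peaks by the authors' enrichment, against 2.06% of all replicated peaks. Reads shared between neighbouring Zfp genes were argued against as the whole cause of the marking, since 60.9% of 110 Zfp genes with no other Zfp gene within 1 Mb were marked, as were 59.4% of 281 clustered ones, against 29.6% of other genes. They were argued against as the whole cause of the strongest peaks, since 9 of 110 isolated genes lay under them against 45 of 20830 other genes (p = 9.53e-12, Fisher's exact test over genes), but 27 of 281 clustered genes did and these held 40 of the 51 peaks, so a part from neighbours stays open, as do paralogs elsewhere in the genome. Zinc finger genes under other symbols were not counted as neighbours, so reads shared with these stay open for both the marking and the strongest peaks. With repeat content, GC content and length as covariates the log2 odds ratio was 2.06 for the marking (95% interval 1.76 to 2.35) and 5.66 for lying under the 100 strongest peaks (4.99 to 6.34). No biological explanation was tested.

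Replicate 1 had fewer and narrower peaks than replicate 2. Its origin from liver, muscle, epidermis, germ line or neural tissue was tested over these 5 tissues together. In replicate 1, 54 of 113 genes of 7 kidney lists held a peak base, where 41.3 were expected at equal gene length, against 7 of 70 genes of those tissues (p = 9.999e-05, the lowest that 10000 permutations allow). The pooled test cannot decide for a single tissue, and widely expressed genes of the kidney lists, such as Actn4 and Ccnd1, may hold peaks in any tissue. Taken singly, none of the 5 lists had a gene above the limit in replicate 1, and no liver or epidermal gene held a peak base. Another tissue or a wrong label stays open, also because the share of genes marked in replicate 1 and not in replicate 2, 0.884%, decides nothing where replicate 2 was the more covered in 97.3% of the genes marked in both. Lower depth or weaker enrichment stays open too: genes marked in replicate 2 alone had a median coverage there of 14.5%, against a lower quartile of 27.3% for genes marked in both, but their selection fixes that order. No biological explanation was tested, and the deposited data held no read counts.

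A further hypothesis was that genes of kidney cell types are marked more often than genes of other tissues. The kidney was not sorted, and the absence of cells of those tissues, such as neurons and glia, was not measured. Over 7 kidney lists 14 of 113 genes were marked, fewer than the 30.1% of all genes, against 0 of 70 over 5 lists for liver, muscle, epidermis, germ line and neurons (p = 0.00107, Fisher's exact test, adjusted p = 0.00171 over 8 comparisons), and in replicate 2 alone 26 of 113 were above the limit against 0 of 70. The kidney genes were longer, with a median of 24.1 kb against 12.4 kb, and at equal gene length 9.15 marked genes were expected (p = 0.00430, permutation within length, adjusted p = 0.00688). With endothelium, erythroid cells and macrophages added, 17 of 157 were marked where 12.0 were expected (p = 0.00850, permutation within length), although no endothelial or erythroid gene was. With steroidogenic genes of adrenal and gonad, of which 1 of 12 was marked, added to the other tissues, 14 of 113 stood against 1 of 82 (p = 0.00710, permutation within length), and that share of 1 in 12 is not far from that of the kidney lists. Some of the marked kidney genes, such as Actn4 and Ccnd1, are widely expressed, and expression was not measured here.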
